A study of Mus musculus with 48 samples.

How the data were processed

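RNA was measured in 48 libraries of mouse embryonic stem cells and their differentiating progeny: 4 genotypes (E14, KAT6A knockout, KAT6B knockout and the double knockout), 4 time points (days 0, 2, 6 and 15) and 3 replicates of each. Per the labels, differentiation was started by withdrawing LIF and growing embryoid bodies, 10 µM all-trans retinoic acid was given from day 4, and cells were plated at day 8 on a coated surface in neuronal medium. Per the labels, 1 µg of total RNA was depleted of ribosomal RNA, made into strand-specific libraries and read as 150 bp paired ends. The authors deposited 1 table of raw gene counts from reads aligned with HISAT2 to GRCm39, and its values are whole numbers. The HISAT2 version, the counting program, its strand setting and the annotation release are not given in the sources used here. Gene coordinates were taken from the deposited table.

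The table had 36983 entries. The 48 that repeat a gene identifier were left out, which kept 36935 genes, of which 4652 had no count in any library. Total counts per library ran from 22.5 to 72.28 M (mega counts), and Rpph1, Rmrp and Malat1 together took 1.46% to 3.58% of them. Counting error is small at this depth, and the spread between replicates set the precision: the biological coefficient of variation was 23.3% for the E14 time course and 19.3%, 21%, 24.6% and 37.8% within days 0, 2, 6 and 15. The bounds given for genes with no count in a group use a floor of 3 counts over the group and cover counting error only.

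Counts were fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept by its expression filter by group, with a minimum count of 10 and a minimum total of 15, and libraries were scaled by trimmed means (TMM). Quasi-likelihood F tests with robust estimation were used, and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with calls at adjusted p under 0.05. The 12 E14 libraries were fitted together to compare days 2, 6 and 15 with day 0 (3 comparisons, 20510 genes). The 12 libraries of each day were fitted together to compare each knockout with E14 (12 comparisons) and the knockouts with each other (12 comparisons), over 18938, 19597, 20537 and 20229 genes. For each knockout, the change of its effect between days 0 and 15 was tested as an interaction (3 comparisons, 20604 to 20695 genes). Levels are TMM-scaled CPM, with a prior count of 2 for log2 values.

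The 24 gene lists (407 genes, 2 of them absent from the table) were written from textbook knowledge before the data were examined, as were the comparisons, the alternatives and the rule for naming genes. The lists were naive pluripotency, formative epiblast, neural progenitor and radial glia, pan-neuronal, presynaptic release, glutamatergic, GABAergic, Hox, retinoic acid response, primitive streak, endoderm, mesenchyme, astrocyte and oligodendrocyte, neural crest and peripheral neuron, blood, endothelium and heart, trophoblast, 2-cell-like state, germline, mitosis and DNA replication, p53 response, KAT6 complexes and MYST acetyltransferases, Polycomb and MLL complexes, imprinted genes and the Y chromosome. Each was tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry, and adjusted over all lists and comparisons of the E14 or the knockout family. Members were also adjusted over the list alone. Unless a count of members says otherwise, it is over all genes. The rule named, for the time course and the knockouts against E14, the 8 genes with the largest change in each direction among called genes with a mean of at least 5 CPM, groups that did not overlap and a gene symbol. It named 4 per direction for other comparisons, and up to 4 called members of each list, or 2 with their values where none was called.

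The tests were tested on simulated data with 200 changed genes. Of 2-fold changes edgeR found 76%, 64%, 42% and 8% at days 0, 2, 6 and 15, and of 4-fold changes 98%, 94%, 88% and 66%. It found 48% and 94% in the E14 time course, and 8% and 70% for an interaction. With no true change beyond those simulated, edgeR made 0 to 12 false calls per design and DESeq2 26 to 49. Because the single knockouts share the E14 libraries, the correlation of their changes was set beside 20 simulated pairs with shared controls and no effect. Each gene was drawn independently in these pairs and in the simulated data with changed genes. Differences shared by many genes of a library were therefore left out, and the false calls in the real data may be more.

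The alternatives were size factors by relative log expression, no filter on low counts, at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, all 48 libraries in 1 fit, only the 2 groups compared in the fit, a term for the replicate number, and leaving out each library in turn. The tests of 2 groups were repeated for all other splits of the compared libraries. For each interaction they were repeated for a random draw of the other splits, 100 with the real one. The 2 libraries of each day farthest from the centre of its first 2 principal components were also left out in turn from the comparisons that share their fit but not their group, a choice made after seeing the data. The replicate number was taken to pair libraries where all 3 same-number correlations of their deviations from the group means were above 0.1. This held for 4 of 27 comparisons: the double knockout with E14 at day 6 (0.145 to 0.46), with the KAT6A knockout at days 2 (0.126 to 0.314) and 6 (0.206 to 0.419), and with the KAT6B knockout at day 0 (0.129 to 0.379). The labels name 3 differentiation experiments but do not say which number marks which. No library was excluded otherwise. Reads, splicing and the edited sites were not analysed here. The values of some genes that the rule names are not reported.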

Results

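RNA sequencing counts were collected from the mouse E14 embryonic stem cell line and from knockout lines derived to lack KAT6A, KAT6B or both. KAT6A and KAT6B are lysine acetyltransferases of the MYST family that modify histone H3. Each of the 4 genotypes was sampled as stem cells (day 0) and at days 2, 6 and 15 of neuronal differentiation, with 3 libraries per group, 16 groups and 48 libraries in all. Total RNA was depleted of ribosomal RNA before sequencing. The libraries came from 3 independent differentiation experiments. Total gene counts per library, in mega counts (M), ran from 22.5 to 72.28 M. In E14 they were 22.5 to 37.15 M at day 0, 34.45 to 51.06 M at day 2, 27.28 to 46.72 M at day 6 and 39.18 to 56.68 M at day 15. In the KAT6A knockout they were 38.94 to 48.46, 35.72 to 43.57, 35.21 to 42.54 and 42.71 to 56.38 M at the same days. In the KAT6B knockout they were 35.44 to 62.83, 33.69 to 47.41, 30.56 to 43.37 and 35.08 to 56.67 M. In the double knockout they were 36.83 to 53.23, 42.59 to 58.9, 36.1 to 57.56 and 47.55 to 72.28 M. Levels below are in CPM, counts scaled to a common library total, given as mean ± SD with n = 3 unless stated, and are scaled within the comparison they belong to. The Kat6a and Kat6b levels and shares and the mean log2 CPM of gene lists are scaled over all 48 libraries instead. Fold changes are edgeR log2 values ± SE, positions are on GRCm39, and floors behind "at least" folds cover counting error only.

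Both target genes kept measurable transcripts in the lines named for their loss. Kat6a (ENSMUSG00000031540, chromosome 8, 23349551 to 23433275, plus strand) was at 142 ± 20 CPM in E14 stem cells and 82.6 ± 4.18 CPM in the KAT6A knockout. This was 58.2% of the E14 mean at day 0, and the share was 50%, 67.5% and 54% at days 2, 6 and 15. In the double knockout Kat6a stood at 75.6%, 66.1%, 70.3% and 60.1% of E14 at the 4 days. At each day the 3 KAT6A knockout and the 3 double knockout libraries lay below the 3 E14 libraries. Kat6b (ENSMUSG00000021767, chromosome 14, 21531502 to 21722546, plus strand) was at 319 ± 62.6 CPM in E14 and 200 ± 15.6 CPM in the KAT6B knockout at day 0. That was 62.9% of E14, with 59.9%, 73.5% and 96.5% at the later days. All 3 KAT6B knockout libraries lay below the 3 E14 libraries at days 0 and 2, and 2 of 3 at day 6. At day 15 replicates 2 and 3 lay below them (79.1 and 73.3 CPM), while replicate 1 (126 CPM) lay above all 3 E14 libraries (90.2 to 105 CPM). In the double knockout the Kat6b shares were 65.8%, 88.9%, 85.1% and 94.8%, with 2, 1, 1 and 2 libraries below all E14 libraries and 1 above them at day 15. In the lines not named for their loss, Kat6a in the KAT6B knockout was at 83.8% to 115% of E14 and Kat6b in the KAT6A knockout at 100% to 124%.

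By edgeR, Kat6a fell in the KAT6A knockout at day 2 (-1.004 ± 0.143, adjusted p = 0.033). In the double knockout it fell at day 2 (-0.62, adjusted p = 0.0461) and at day 15 (-0.75, adjusted p = 0.0276), and Kat6b fell at day 0 (-0.64, adjusted p = 0.0419). Each of these 4 calls was lost in at least 3 of the 6 fits that left out 1 library, with adjusted p up to 0.365, 0.195, 0.132 and 0.142. Kat6b in the KAT6B knockout gave -0.71, -0.75, -0.44 and -0.06 at the 4 days, with adjusted p of 0.14, 0.622, 0.251 and 0.892. A count over a whole gene cannot show an edited exon or a lost protein, so these values neither identify nor exclude the edit in each line.

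**Figure D1:**
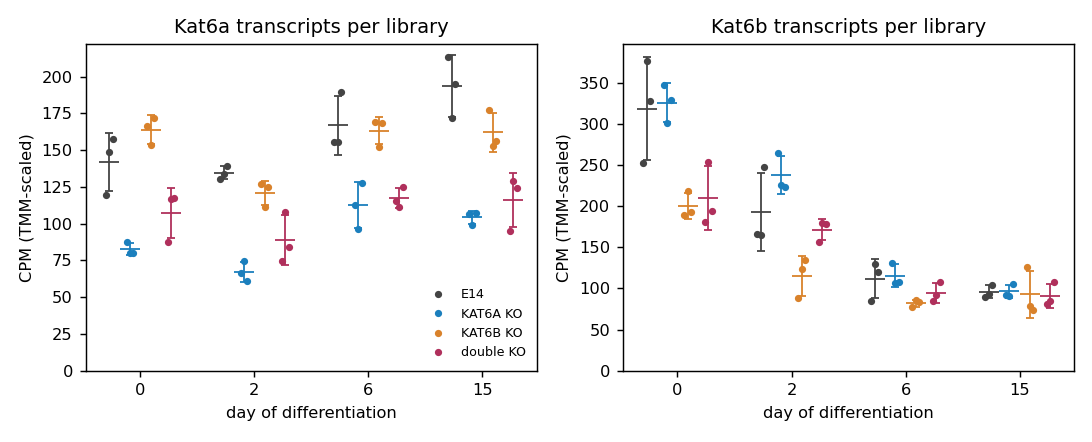
Kat6a and Kat6b levels in CPM (vertical axis) by day and genotype, with a point per library and bars at the mean ± SD of 3 libraries. Kat6a in the KAT6A knockout lay at 50% to 67.5% of the E14 mean.

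The time course of the E14 line gives the differentiation against which the knockouts were read. Between days 0 and 2, genes of the naive stem cell state fell while genes of the formative epiblast rose. Klf4, a naive pluripotency factor, fell from 147 ± 26.5 to 16.6 ± 7.85 CPM, and Tbx3, another, from 107 ± 23.3 to 19 ± 6.29 CPM. Socs3, a target of signalling by LIF, the factor withdrawn to start differentiation, fell by 3.47 on the log2 scale (adjusted p = 1.8e-05). Fgf5, a marker of the epiblast after implantation, rose from 5.00 ± 2.82 to 61.1 ± 5.74 CPM, a log2 change of 3.62 ± 0.38 (adjusted p = 8.28e-05). Otx2, a transcription factor of the formative state, rose by 2.72 ± 0.62 and the DNA methyltransferase gene Dnmt3b by 1.36 ± 0.29.

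Of the 20 naive pluripotency genes, 8 fell and 0 rose at day 2, and 12 fell when adjusted over the list alone (median -0.91, camera adjusted p = 6.35e-07). Of the 11 formative epiblast genes, 6 rose and 0 fell, and 7 rose when adjusted over the list alone (median 1.17, adjusted p = 7.44e-06). Mesenchyme genes (4 of 15 fell, median -1.45, adjusted p = 1.27e-06) and trophoblast genes (6 of 11 fell, median -1.94, adjusted p = 3.51e-05) were lower as groups, with 6 each when adjusted over the list alone. Col1a1, a fibrillar collagen gene, went from 162 ± 48.2 to 10.9 ± 0.69 CPM. The naive, formative, mesenchyme and trophoblast calls were lost with an estimated correlation, at adjusted p = 0.305, 0.079, 0.24 and 0.24. At day 2, 4426 of 20510 tested genes changed (1948 higher, 2478 lower), and the 2 groups did not overlap for 41.1% of genes, where chance gives 10%. The count was 2082 without E14 day 0 replicate 3, 2115 without day 2 replicate 1 and 1985 without day 2 replicate 2.

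At day 6, after retinoic acid had been added at day 4, the retinoic acid response and the Hox genes rose sharply. Cyp26b1, which encodes an enzyme that degrades retinoic acid, rose from 0.99 ± 0.49 to 397 ± 214 CPM. Rarb, a retinoic acid receptor gene, rose by 7.01 ± 0.36 (adjusted p = 3.88e-08), and Stra6, which encodes a retinol transporter, by 5.17 ± 0.25 (adjusted p = 3.69e-08). Hoxb4, of the clusters that pattern the body axis, rose from 0.45 ± 0.14 to 102 ± 25.1 CPM (7.76 ± 0.30, adjusted p = 9.27e-09). Of 16 retinoic acid response genes 15 rose and 1 fell, over all genes and when adjusted over the list alone (median 5.43, camera adjusted p = 3.72e-26). Of 33 Hox genes 23 rose, and 24 when adjusted over the list alone (median 5.12, adjusted p = 3.72e-26). Both calls held with an estimated correlation, at adjusted p = 0.0105 and 0.0403.

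Neural progenitor genes rose at day 6 as well. Pax6, a neural progenitor transcription factor, rose from 8.26 ± 1.42 to 107 ± 47.3 CPM. Dbx1 and Wnt1, which are expressed in the early neural tube, had no count at day 0 and were at least 1720-fold and at least 318-fold higher. Of 20 neural progenitor genes 15 rose, and 15 rose and 1 fell when adjusted over the list alone (median 2.50, adjusted p = 3.91e-05). Genes of primitive and visceral endoderm also rose, 17 of 18 over all genes and over the list alone (median 3.53, adjusted p = 9.26e-14), among them Gata4 (3.53 ± 0.28). Tdgf1, a Nodal co-receptor gene, fell by 5.44 and T, the primitive streak factor Brachyury, fell by 6.81 on the log2 scale. Of the naive genes 19 of 20 fell, and 20 when adjusted over the list alone (median -2.90, adjusted p = 2.01e-12). The neural progenitor, endoderm and naive calls were lost with an estimated correlation, at adjusted p = 0.275, 0.0995 and 0.24. In all, 10257 genes changed at day 6 (5290 higher, 4967 lower), and the groups did not overlap for 53.9% of genes.

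By day 15 neuronal and synaptic genes had risen. Map2, a microtubule protein of dendrites, rose from 13.3 ± 2.78 to 617 ± 177 CPM and the adhesion gene Ncam1 from 27.3 ± 6.4 to 618 ± 126 CPM. Fabp7, a fatty acid binding protein of radial glia, rose by 10.13 ± 0.23 (adjusted p = 7.79e-12). The glutamate receptor gene Grin2b rose by 6.82 ± 0.27 and Gad2, an enzyme of GABA synthesis, by 6.50 ± 0.64. Lrrc7, a postsynaptic scaffold gene, and Tnr, of the neural extracellular matrix, had no count at day 0 and were at least 1050-fold and at least 805-fold higher. All 18 presynaptic genes rose, over all genes and over the list alone (median 4.09, camera adjusted p = 1.91e-13). Of 20 pan-neuronal genes 17 rose and 1 fell, with 18 and 1 adjusted over the list alone (median 3.59, adjusted p = 4.3e-10). Glutamatergic genes (13 of 16 rose, 2 fell, median 3.89, adjusted p = 2.36e-05) and GABAergic genes (8 of 11 rose, median 3.02, adjusted p = 0.0181) followed, with 13 rising and 2 falling, and 9 rising and 1 falling, when adjusted over the list alone. These 4 neuronal calls were lost with an estimated correlation, at adjusted p = 0.188, 0.204, 0.176 and 0.243.

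Genes of other cell types had risen in the day 15 cultures as well. All 15 mesenchyme genes rose (median 3.54, adjusted p = 8.16e-06), among them Col1a2 at 655 ± 348 CPM, and 13 of 18 endoderm genes rose and 1 fell (median 4.22, adjusted p = 1.03e-05), among them Gata4 at 314 ± 81.9 CPM. Of 11 astrocyte and oligodendrocyte genes 9 rose and 1 fell (median 3.68, adjusted p = 0.000126), among them Gfap, the astrocyte intermediate filament gene, at 133 ± 73.7 CPM. All 18 genes of mitosis and DNA replication fell (median -2.15, adjusted p = 1.65e-15), among them the mitotic kinase gene Plk1 (-2.26 ± 0.11) and the replication helicase gene Mcm2 (-2.69 ± 0.15). Of 20 naive genes 19 fell (median -4.52, adjusted p = 3.31e-09), among them Esrrb (-4.53 ± 0.35) and Tet1 (-3.56 ± 0.19). The counts were the same when adjusted over the list alone for these 5 lists. All 5 calls were lost with an estimated correlation, at adjusted p = 0.275, 0.24, 0.0995, 0.0513 and 0.243. At day 15, 14289 genes changed (7478 higher, 6811 lower), and the groups did not overlap for 72.5% of genes.

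The targets and their complexes moved with time in E14. Kat6b fell, with log2 changes of -0.74, -1.498 and -1.70 at days 2, 6 and 15 (adjusted p = 0.0144, 3.04e-05 and 2.87e-06), and the day 2 call was lost without E14 day 0 replicate 3 or day 2 replicate 1 or 2 (adjusted p up to 0.0768). Kat6a rose by 0.48 at day 15 (adjusted p = 0.00381). Of 14 genes of the KAT6 complexes and MYST acetyltransferases, 10 fell and 2 rose by day 15, also when adjusted over the list alone (median -0.72, camera adjusted p = 0.00523). Of 23 genes of Polycomb and MLL complexes, 13 fell and 6 rose, also over the list alone (median -0.74, adjusted p = 0.0311). Jarid2, a Polycomb partner, fell by 3.09. Both complex calls were lost with an estimated correlation, at adjusted p = 0.204 each.

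Some libraries stood apart from their groups. On the first 2 principal components of each day, E14 replicate 1 (-83.9 on the first component, 23.2% of the variance) and KAT6B knockout replicate 2 (50.3 on the second) lay apart at day 0. At day 2 KAT6B knockout replicate 1 (-56.2 on the first component, 21.6% of the variance) and double knockout replicate 2 (51.4 on the second, with replicate 1 at 44.5) did. At day 6 KAT6B knockout replicate 1 (82.6 on the first component, 32.8% of the variance) and E14 replicate 1 (81.1 on the second) lay apart. At day 15 KAT6B knockout replicate 2 (125 on the first component, 46.4% of the variance) and KAT6B knockout replicate 1 (-110 on the second) did. The latter, whose Kat6b level exceeded that of each E14 library, was at -42.8 on the first component, where E14 libraries were at -108 to -53.5 and the other KAT6B knockout libraries at 41.2 and 125. Replicates varied more at day 15 than before: the biological coefficient of variation was 19.3%, 21%, 24.6% and 37.8% at days 0, 2, 6 and 15.

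**Figure D2:**
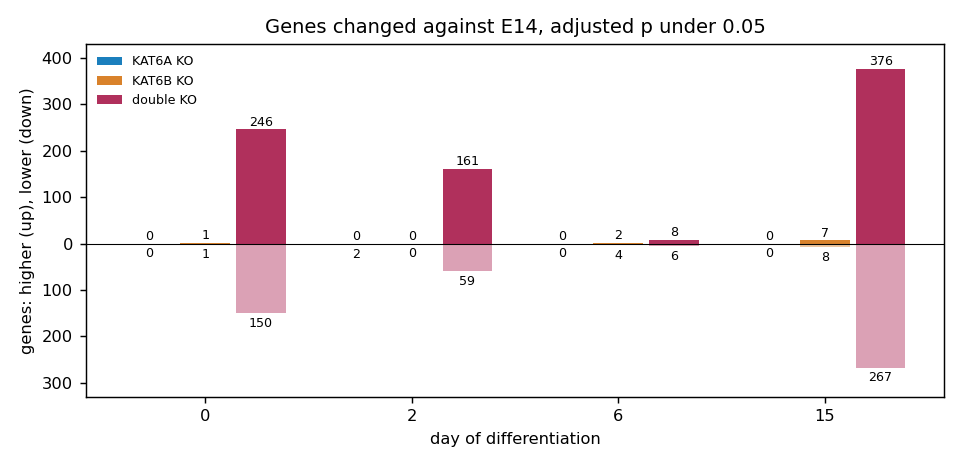
Number of genes changed by edgeR (adjusted p under 0.05, higher and lower) for each knockout line against E14 at each day, with bars above 0 for higher and below 0 for lower genes. The double knockout had 396, 220, 14 and 643 changed genes at days 0, 2, 6 and 15.

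The double knockout against E14 in stem cells shows the state before differentiation. Krt7, a keratin of simple and trophoblast epithelia, rose from 5.70 ± 1.45 to 25.7 ± 5.14 CPM (2.18 ± 0.21, adjusted p = 0.000442). H19, an imprinted noncoding RNA, rose from 332 ± 68.1 to 1087 ± 421 CPM. Nxf7 (2.32 ± 0.26) and Magea9 (2.15 ± 0.25), members of multigene families whose counts cannot be given to 1 member with certainty, rose as well. Ntn1, which encodes the guidance cue netrin, fell from 51.4 ± 3.85 to 12.5 ± 0.76 CPM (-2.04 ± 0.25, adjusted p = 0.00217). Kbtbd11 fell by 1.68, Mras by 1.74 and Stmn2 by 0.70 on the log2 scale. Jade3, of the scaffold family that binds MYST acetyltransferases, rose by 0.64.

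As groups at day 0, by the preset correlation alone, 3 of 11 trophoblast genes rose and 7 when adjusted over the list alone (median 0.89, camera adjusted p = 1.27e-08), among them Hand1 at 40.6 ± 10.7 against 10.7 ± 6.29 CPM. Of 14 mesenchyme genes 4 rose and 8 over the list alone (median 0.69, adjusted p = 2.55e-06), among them Acta2 (1.86 ± 0.30) and Col1a1 (1.63 ± 0.34). Of 20 naive genes 4 fell and 7 over the list alone (median -0.37, adjusted p = 1.42e-06): Klf4 fell by 0.66, Esrrb by 0.43, Nr0b1 by 0.75 and Tfcp2l1 by 0.60. Y chromosome genes (1 of 7 rose, 4 over the list alone, median 1.31, adjusted p = 1.58e-05) and 2-cell-like state genes (0 changed over all genes or over the list alone, median 0.92, adjusted p = 0.000417) were higher as groups. With an estimated correlation the 5 calls were lost, at adjusted p = 0.149, 0.223, 0.289, 0.26 and 0.57. Each of the 5 held by the preset correlation in all 6 fits that left out 1 library. In all, 13 lists were called at day 0, of which 6 held in all 6 fits. For the retinoic acid response list the median (-0.12) and the test (up, adjusted p = 0.687) differed in sign.

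In all, 396 of 18938 genes changed in the double knockout at day 0 (246 higher, 150 lower), and the groups did not overlap for 18.5% of genes, where chance gives 10%. The count turned on the libraries: it was 157, 1942 and 187 without E14 replicates 1, 2 and 3, and 140, 80 and 119 without double knockout replicates 1, 2 and 3. Of the 44 calls among named genes, 10 held in all 6 of those fits, among them Krt7, Nxf7, Magea9, H19, Ntn1, Kbtbd11, Stmn2, Mras and Jade3. Hand1 reached adjusted p = 0.122, Col1a1 0.19, Acta2 0.0501, Klf4 0.108, Esrrb 0.156, Nr0b1 0.142 and Tfcp2l1 0.145 in the least favourable fit. With a term for the replicate number more genes changed at day 0.

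At day 2 genes of trophoblast were among those that rose in the double knockout. Hand1, a trophoblast and heart transcription factor, rose from 1.21 ± 0.57 to 7.42 ± 2.44 CPM, Gata2 from 1.52 ± 0.21 to 4.76 ± 0.90 CPM and Plet1, a marker of early trophoblast, from 3.10 ± 0.31 to 7.66 ± 2.41 CPM. Lgals9, which encodes a galectin, rose by 2.25 ± 0.23 (adjusted p = 0.000702), and Rhox6, of an X-linked homeobox family, by 2.04 ± 0.27 (adjusted p = 0.00344). The imprinted genes Igf2 and H19 rose by 1.56 ± 0.31 and 1.74 ± 0.30, while the imprinted Grb10 fell from 52.1 ± 8.23 to 19.3 ± 2.07 CPM. Otx2 fell from 195 ± 33.3 to 114 ± 12.6 CPM, and Adamts15, a matrix protease gene, fell by 1.28 (adjusted p = 0.00344).

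As groups at day 2, 4 of 11 trophoblast genes rose and 6 when adjusted over the list alone (median 0.95, camera adjusted p = 2.55e-10), and the call held with an estimated correlation (adjusted p = 0.0318). Of 11 formative genes 1 fell and 7 over the list alone (median -0.78, adjusted p = 1.36e-06). Genes of blood, endothelium and heart (1 of 13 rose, 6 over the list alone, median 0.56, adjusted p = 7.52e-06), the 2-cell-like state (0 of 11, 2 over the list alone, median 1.01, adjusted p = 4.55e-06) and the Y chromosome (2 of 7 rose, 3 over the list alone, median 1.19, adjusted p = 4.68e-05) were higher as groups. With an estimated correlation these 4 calls were lost, at adjusted p = 0.272, 0.0758, 0.229 and 0.366. Naive genes, lower at day 0, were higher as a group at day 2 in the double knockout (0 of 20 over all genes or the list alone, median 0.26, adjusted p = 0.0468), which an estimated correlation ended (adjusted p = 0.718). The call was also lost without E14 replicate 1 or 2 or double knockout replicate 1 or 2 (adjusted p up to 0.19).

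At day 2, 220 of 19597 genes changed (161 higher, 59 lower), and the groups did not overlap for 22.5% of genes. The count was 9, 7 and 79 without E14 replicates 1, 2 and 3, and 92 and 40 without double knockout replicates 1 and 2, of which the latter lay apart. Without KAT6B knockout replicate 1, a choice made after seeing the data, it was 440. Of 34 named calls, those of Lgals9, Adamts15 and Rhox6 held in all 6 fits. Without 1 library the calls of Hand1, Gata2, Plet1, Igf2, H19, Grb10 and Otx2 reached adjusted p of 0.0799, 0.0781, 0.135, 0.15, 0.0812, 0.0727 and 0.165.

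At day 6 few genes passed the test in the double knockout. Rsad2, which encodes the antiviral protein viperin, rose from 2.14 ± 0.25 to 9.26 ± 1.9 CPM, Igtp, a GTPase gene, from 11.2 ± 1.49 to 30.9 ± 7.75 CPM and Lgals3bp, which encodes a galectin-binding glycoprotein, from 12.1 ± 2.89 to 38.0 ± 9.23 CPM. Slfn5 and Helz2 rose by 1.68 ± 0.24 and 0.82 ± 0.13. Grb10 fell from 104 ± 25.2 to 19 ± 4.5 CPM, Rims2, of the presynaptic active zone, by 1.20, and Fgf15 fell by 2.54 on the log2 scale. Kdm1a, the histone demethylase LSD1, fell from 206 ± 1.93 to 122 ± 6.68 CPM (-0.75 ± 0.09, adjusted p = 0.0251) and its neighbour Luzp1 by 0.79.

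As groups at day 6, by the preset correlation alone, neural progenitor genes were lower (0 of 20 over all genes, 2 fell over the list alone, median -0.77, camera adjusted p = 2.03e-07). Trophoblast genes (0 of 11, 3 rose over the list alone, median 0.64, adjusted p = 5.03e-06) and Y chromosome genes (0 of 7, 5 rose over the list alone, median 1.09, adjusted p = 1.71e-08) were higher. None of these 3 calls held with an estimated correlation, at adjusted p = 0.427, 0.149 and 0.223. Y chromosome genes were also higher in the KAT6A knockout at days 2 and 6 (camera adjusted p = 0.0137 and 0.000354). In the KAT6B knockout they were higher at days 0, 2 and 6 (camera adjusted p = 0.00733, 0.00749 and 0.00712). Of these single knockout calls only that of the KAT6A knockout at day 6 held in all 6 fits, and none held with an estimated correlation. In the double knockout at day 6 mesenchyme genes (camera adjusted p = 0.00663) and blood, endothelium and heart genes (0.00443) were also higher. Both calls were lost without E14 replicate 2 (adjusted p = 0.35 and 0.0655) and with an estimated correlation. In all, 14 of 20537 genes changed (8 higher, 6 lower), and the groups did not overlap for 11.8% of genes. The count was 0, 6 and 1 without E14 replicates 1, 2 and 3, and 0, 3 and 0 without the double knockout replicates. No named call held in all 6 fits; Kdm1a and Luzp1 reached adjusted p = 0.12 and Rsad2 0.224. Without KAT6B knockout replicate 1, left out after seeing the data, 31 genes changed. With the replicate block 39 genes changed, Grb10 was at -2.46 (adjusted p = 0.0528) and Kat6a passed at -0.54 (adjusted p = 0.037).

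At day 15 genes of neural progenitors were among those that fell in the double knockout. Hes5, a Notch target of neural progenitors, fell from 20.3 ± 9.06 to 0.59 ± 0.45 CPM (-5.07 ± 0.77, adjusted p = 0.0218). Sox1, an early neural factor, fell from 23.2 ± 2.54 to 0.96 ± 0.52 CPM. Prom1 and Slc1a3, which are expressed in radial glia, fell by 2.68 and 3.02 on the log2 scale. Among genes of young neurons, the sensory neuron factor Pou4f1 fell by 3.83, Reln, which encodes reelin, from 165 ± 53.3 to 10.4 ± 4.86 CPM, and the chemokine receptor gene Cxcr4 by 4.09. Ptx3, a pentraxin gene, rose from 1.76 ± 0.31 to 30.6 ± 13 CPM (4.11 ± 0.51, adjusted p = 0.0182). Bgn, a matrix proteoglycan gene, rose from 20.4 ± 6.37 to 185 ± 97.7 CPM, and the chemokine gene Ccl7 and the Wnt agonist gene Rspo3 by 3.62 ± 0.77 and 3.19 ± 0.68.

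Of 20 neural progenitor genes 7 fell at day 15, and 14 fell and 1 rose when adjusted over the list alone (median -2.50, camera adjusted p = 4.53e-13). Their mean log2 CPM was 4.69 ± 0.13 in E14, 3.63 ± 0.36 in the KAT6A knockout, 2.85 ± 0.86 in the KAT6B knockout and 2.32 ± 0.62 in the double knockout. Pan-neuronal genes (0 of 20 over all genes or the list alone, median -1.46, adjusted p = 0.000374), glutamatergic genes (2 of 16 fell, 6 over the list alone, median -1.45, adjusted p = 5.67e-05) and astrocyte and oligodendrocyte genes (2 of 11 fell, 4 over the list alone, median -2.21, adjusted p = 0.00297) were lower as groups. Mesenchyme genes were higher (0 of 15 over all genes or the list alone, median 1.07, adjusted p = 0.00298). With an estimated correlation the 5 calls were lost, at adjusted p = 0.247, 0.707, 0.518, 0.392 and 0.615. By the preset correlation each held in all 6 fits that left out 1 library, with a highest adjusted p for neural progenitors of 1.47e-10. Of the 11 lists called at day 15, only these 5 did.

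In all, 643 of 20229 genes changed in the double knockout at day 15 (376 higher, 267 lower), and the groups did not overlap for 42% of genes, where chance gives 10%. This count rested on nearly every library. It was 0, 17 and 0 without E14 replicates 1, 2 and 3, and 0, 0 and 102 without double knockout replicates 1, 2 and 3, and no named call held in all 6 fits. Hes5 and Prom1 reached adjusted p = 0.099, Sox1 0.108 and Ptx3 0.099. With the replicate block 0 genes changed. Same-number correlations of these libraries ran from -0.22 to 0.22, so whether the numbers pair them is undecided. Without KAT6B knockout replicate 1, which lay apart, 2579 genes changed; this setting was chosen after seeing the data.

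**Figure D3:**
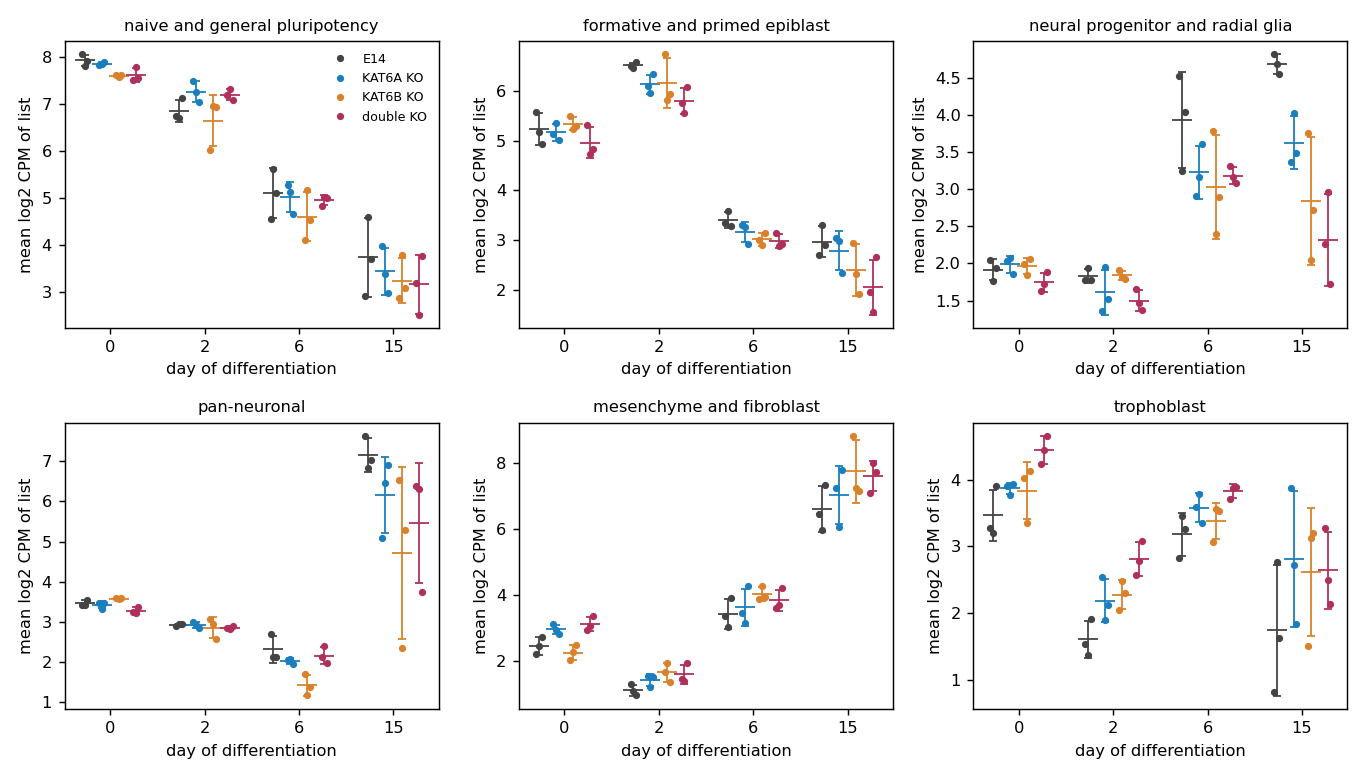
Mean log2 CPM of gene lists (vertical axis) by day and genotype, with a point per library and bars at the mean ± SD of 3 libraries. Neural progenitor genes at day 15 were at 4.69 ± 0.13 in E14 and 2.32 ± 0.62 in the double knockout.

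The KAT6A knockout was compared with E14 in the same way. Besides Kat6a, only Grb10, an imprinted adaptor gene, passed the test: at day 2 it fell from 52.1 ± 8.23 to 15.2 ± 3.45 CPM (-1.77 ± 0.23, adjusted p = 0.0253). As groups, by the preset correlation alone, mesenchyme genes were higher in stem cells (0 of 14, 3 rose over the list alone, median 0.47, camera adjusted p = 2.55e-06). Formative genes were lower at day 2 (0 of 11 over all genes or the list alone, median -0.39, adjusted p = 0.00284). Naive genes were higher at day 2 (0 of 20 over all genes or the list alone, median 0.49, adjusted p = 0.00244). Neural progenitor genes were lower at day 6 (0 of 20 over all genes or the list alone, median -0.81, adjusted p = 1.1e-06). They were lower again at day 15 (0 of 20, with 4 falling and 1 rising over the list alone, median -1.12, adjusted p = 5.47e-06), as were astrocyte and oligodendrocyte genes (0 of 11, 5 fell over the list alone, median -1.47, adjusted p = 2.07e-05). Genes of the p53 response were higher at day 15 (0 of 15, 1 rose over the list alone, median 0.37, adjusted p = 6.23e-06). With an estimated correlation these 7 calls were lost, at adjusted p = 0.223, 0.499, 0.573, 0.44, 0.469, 0.26 and 0.32. By the preset correlation each held in all 6 fits that left out 1 library, except the naive call, lost without KAT6A knockout replicate 1 (adjusted p = 0.0914). In this line 4, 7, 9 and 11 lists were called at days 0, 2, 6 and 15, of which 1, 2, 4 and 5 held in all 6 fits. Mesenchyme genes (median 0.66, adjusted p = 0.015) and trophoblast genes (median 1.11, adjusted p = 0.0034) were also higher at day 15, with 0 of 15 and 0 of 11 over all genes or the list alone. An estimated correlation ended both calls (adjusted p = 0.709 and 0.615). The mesenchyme call was lost without E14 replicate 2 or KAT6A knockout replicate 3 (adjusted p up to 0.413), and the trophoblast call without KAT6A knockout replicate 1 (adjusted p = 0.196). At day 6 trophoblast genes (camera adjusted p = 0.0034, held in all 6 fits) and endoderm genes (0.00199) were higher too. That endoderm call was lost without E14 replicate 3 or KAT6A knockout replicate 2 (adjusted p up to 0.818). Neither day 6 call held with an estimated correlation.

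By edgeR 0, 2, 0 and 0 genes changed in the KAT6A knockout at days 0, 2, 6 and 15, against 898, 2011, 1089 and 2305 at an unadjusted p under 0.05, while DESeq2 called 5, 28, 2 and 280. The groups did not overlap for 9.77%, 20.7%, 11.5% and 26.4% of genes, where chance gives 10%. The call of Grb10 was lost without E14 replicate 1, E14 replicate 2 or any KAT6A knockout replicate (adjusted p up to 0.365). The day 0 count was 1 without E14 replicate 1, and 1 gene passed without KAT6B knockout replicate 2, left out after seeing the data. The day 2 count was 1 without E14 replicate 3 and 0 without any of the other 5 libraries.

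The KAT6B knockout against E14 gave few called genes. In stem cells Plekhg1 rose from 37.1 ± 3.94 to 73.9 ± 5.64 CPM and Lars2, a mitochondrial leucyl-tRNA synthetase gene, fell from 52.4 ± 8.45 to 20.2 ± 4.74 CPM. At day 6 Myl7, an atrial myosin light chain gene, rose by 1.85 ± 0.25 and the keratin gene Krt8 by 1.15 ± 0.17. At that day Grb10 fell from 104 ± 25.2 to 12.9 ± 5.56 CPM, and Acot7, Ap3b2 and Kdm1a by 1.22, 0.86 and 0.63 on the log2 scale. At day 15 Sox2, a factor of neural progenitors, fell from 61.6 ± 4.89 to 9.65 ± 4.04 CPM (-2.67 ± 0.35, adjusted p = 0.0295). Lmx1b, of hindbrain and midbrain neurons, Hopx, of radial glia, and Nrarp, a Notch target, fell by 2.83, 2.56 and 2.60. Kank2 rose from 67.6 ± 6.72 to 158 ± 19.3 CPM (1.22 ± 0.12, adjusted p = 0.0131), Myrf, a regulator of myelin genes, rose by 1.93 ± 0.23, and Pde1b, a phosphodiesterase gene, fell by 1.84.

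As groups in the KAT6B knockout, by the preset correlation alone, naive genes were lower at day 0 (0 of 20, 11 fell over the list alone, median -0.36, camera adjusted p = 1.57e-09). Trophoblast genes (0 of 11, 2 rose over the list alone, median 0.55, adjusted p = 1.1e-06) and mesenchyme genes (0 of 14, 3 rose over the list alone, median 0.44, adjusted p = 2.46e-06) were higher at day 2, beside a day 2 library, replicate 1, that lay apart. Naive genes were lower at day 2 (0 of 20 over all genes or the list alone, median -0.17, adjusted p = 0.00183). At day 6, where replicate 1 also lay apart, pan-neuronal genes (0 of 20, 9 fell over the list alone, median -0.96, adjusted p = 6.45e-10), neural progenitor genes (0 of 20, 6 fell over the list alone, median -1.01, adjusted p = 7.52e-06) and 2-cell-like state genes (0 of 12, 9 fell over the list alone, median -1.42, adjusted p = 1.89e-10) were lower. With an estimated correlation these 7 calls were lost, at adjusted p = 0.229, 0.0756, 0.223, 0.57, 0.223, 0.497 and 0.289. Formative genes were also lower at day 2 (camera adjusted p = 6.58e-06, mean log2 CPM 6.16 ± 0.50 against 6.51 ± 0.05 in E14). At day 6, 5 lists were higher. Among them were mesenchyme (camera adjusted p = 0.00363), endoderm (0.0111), trophoblast (0.0319) and blood, endothelium and heart genes (0.00749). An estimated correlation ended these calls too.

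At day 15, where KAT6B knockout replicates 1 and 2 lay apart in different directions, neural progenitor genes were lower by the preset correlation alone (0 of 20, with 13 falling and 1 rising over the list alone, median -1.79, camera adjusted p = 2.06e-09). So were astrocyte and oligodendrocyte genes (0 of 11, 7 fell over the list alone, median -2.65, adjusted p = 2.55e-06) and pan-neuronal genes (0 of 20 over all genes or the list alone, median -1.68, adjusted p = 2.03e-07). Genes of the p53 response (0 of 15, 8 rose over the list alone, median 0.53, adjusted p = 5.03e-06) and mesenchyme genes (0 of 15, 2 rose over the list alone, median 1.30, adjusted p = 0.000197) were higher. None of the 5 held with an estimated correlation, at adjusted p = 0.3, 0.229, 0.57, 0.3 and 0.57. Each KAT6B knockout list call given here for days 0 to 15 held by the preset correlation in all 6 fits that left out 1 library, except those of naive genes at day 2, lost without E14 replicate 3 or KAT6B knockout replicate 1 (adjusted p up to 0.841), and of mesenchyme genes at day 15, lost without KAT6B knockout replicate 1 (adjusted p = 0.0897). The day 6 calls of mesenchyme, endoderm, trophoblast and blood, endothelium and heart genes were further exceptions. Each was lost without at least 1 library (adjusted p up to 0.0809, 0.26, 0.224 and 0.0558). In this line 7, 10, 12 and 9 lists were called at days 0, 2, 6 and 15, of which 1, 5, 3 and 7 held in all 6 fits.

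By edgeR 2, 0, 6 and 15 genes changed in the KAT6B knockout at days 0, 2, 6 and 15, against 2240, 798, 2680 and 4048 at an unadjusted p under 0.05, while DESeq2 called 194, 23, 534 and 1720. The groups did not overlap for 13.2%, 10%, 17.5% and 29.1% of genes, where chance gives 10%. At day 0 the count was 1164 without E14 replicate 2, 0 without E14 replicate 3 or KAT6B knockout replicate 1, and 5 and 4 without KAT6B knockout replicates 2, which lay apart, and 3. At day 2 it was 3 without KAT6B knockout replicate 1. At day 6 it was 3 without E14 replicate 3 and 0 without any of the other 5 libraries. At day 15 it was 3, 2 and 3 without E14 replicates 1, 2 and 3, and 1949, 0 and 3 without KAT6B knockout replicates 1, 2 and 3. With the replicate block the count was higher at days 0 and 6 and was 0 at day 15. None of the calls named for this line held in all 6 fits; Grb10 reached adjusted p = 0.174, Sox2 0.12, Kank2 0.0979 and Plekhg1 0.139.

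The single knockouts were also compared with each other across genes. The log2 changes of the KAT6A and KAT6B knockouts correlated at r = 0.586, 0.448, 0.342 and 0.734 at days 0, 2, 6 and 15. Both use the same 3 E14 libraries of each day, which cannot be split, and counts simulated with shared controls and no effect gave mean r of 0.524, 0.499, 0.505 and 0.496. The covariance was 0.103, 0.0834, 0.0916 and 0.456, against simulated means of 0.0649, 0.0692, 0.0838 and 0.143. The 20 simulated values of r ran from 0.512 to 0.545, 0.477 to 0.515, 0.489 to 0.522 and 0.485 to 0.506. The real r lay above them at days 0 and 15 and below them at days 2 and 6. The covariance lay above the highest simulated value at each day (0.0686, 0.0725, 0.0896 and 0.148). Each gene was simulated independently, so these ranges leave out differences shared by many genes of a library and cannot place r against chance. At day 2 r was 0.686 without E14 replicate 3 and 0.244 without KAT6B knockout replicate 2. At day 6 it was 0.657 without E14 replicate 3, 0.092 without KAT6A knockout replicate 3 and 0.213 without KAT6B knockout replicate 2, and at day 0 it was 0.473 without KAT6B knockout replicate 3. Genes are not independent replicates, and 0 genes were called in both lines by edgeR at any day; DESeq2 called 2, 4, 2 and 227 in the same direction.

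Comparing the knockout lines directly, a pair of neighbouring genes on chromosome 4 separated the KAT6B knockout and the double knockout from the KAT6A knockout. Luzp1 (136197072 to 136282091, plus strand), a leucine zipper protein of the cytoskeleton, and Kdm1a (136277851 to 136330034, minus strand) overlap by 4241 bp. In the double knockout against the KAT6A knockout Luzp1 fell by 0.99, 1.05, 1.17 and 1.18 on the log2 scale at days 0, 2, 6 and 15, and Kdm1a fell by 1.12, 0.85 and 0.95 at days 0, 2 and 6. In the KAT6B knockout against the KAT6A knockout Luzp1 fell by 1.01, 0.90 and 0.99 at days 0, 2 and 6, and Kdm1a by 1.00 at day 0 and 0.82 at day 6. Part of these differences lay in the KAT6A knockout, where Luzp1 was at 0.44, 0.14, 0.38 and 0.78 against E14 (adjusted p = 0.931, 0.669, 0.809 and 0.287). Against E14 at day 15 Luzp1 was at -0.40 in the double knockout (adjusted p = 0.0968). The day 6 calls in the double knockout against the KAT6A knockout (adjusted p = 0.000846 for Luzp1 and 0.00107 for Kdm1a) held in each fit that left out 1 library. The other calls of the pair were each lost without at least 1 library.

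Other genes separated the double knockout from the single ones in stem cells. Against the KAT6B knockout it had higher Igf2 (2.61 ± 0.39), Col1a1 (2.23 ± 0.35), Acta2 (2.20 ± 0.31) and Col1a2 (1.88 ± 0.31), the last 3 of mesenchyme and fibroblasts. Against the KAT6A knockout it had higher Krt7 (1.57 ± 0.20) and H19 (1.49 ± 0.22) and lower Ntn1 (-1.71 ± 0.25). Chosen after its values were seen, Magea9 rose against the KAT6A knockout at day 2 (1.91 ± 0.29). At day 2 against the KAT6B knockout Dusp27 rose by 1.29 ± 0.17 and Adamts15 fell by 1.19. Kat6a was higher in the KAT6B than in the KAT6A knockout at day 0 (1.01 ± 0.13, adjusted p = 0.00888), as were Sned1 and Pdzd2 (0.92 ± 0.13 and 0.91 ± 0.14).

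Few genes passed between knockout lines. By edgeR the double knockout differed from the KAT6A knockout in 10, 3, 2 and 1 genes at days 0, 2, 6 and 15, with 1433, 1518, 505 and 1020 at an unadjusted p under 0.05 and 127, 110, 11 and 61 by DESeq2. It differed from the KAT6B knockout in 12, 2, 0 and 0 genes (1140, 1789, 2677 and 945 unadjusted, and 140, 219, 641 and 72 by DESeq2). The single knockouts differed in 5, 1, 2 and 0 genes (916, 2013, 2819 and 780 unadjusted, and 32, 134, 460 and 31 by DESeq2). At day 0 the 10 genes were 0, 5 and 2 without KAT6A knockout replicates 1, 2 and 3 and 5 without double knockout replicate 2. The 12 genes were 0, 0 and 7 without KAT6B knockout replicates 1, 2 and 3 and 1 without double knockout replicate 2. The 5 genes were 1 without any KAT6A knockout replicate, and 0 and 8 without KAT6B knockout replicates 1 and 3. At day 2 the double knockout against the KAT6A knockout gave 1 without any KAT6A knockout replicate, and 0, 1 and 35 without double knockout replicates 1, 2 and 3. Against the KAT6B knockout it gave 0 without replicate 1 or 2 of either line, and 5 and 7 without the third of each. With the replicate block the 12 genes at day 0 were 27, with Col1a2 at adjusted p = 0.0532, and the 3 genes against the KAT6A knockout at day 2 were 5. The day 15 gene, Luzp1, was lost without any of the 6 libraries.

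Whether the double knockout effect itself differed between days 15 and 0 was tested by an interaction. It did for 518 of 20695 genes (212 higher, 306 lower). Of the calls among named genes 2 held in all 12 fits that left out 1 library: Cxcr4 and Mir9-3hg, the host gene of a neural microRNA, at -4.50 and -4.58. Gfap (-5.48) and Rfx4, a factor of neural tube development (-4.55), fell as well, and Rspo3 (3.89), Loxl4 (3.51), Angptl4 (3.11) and Muc3 (2.63) rose. The count was 156, 1130 and 133 without E14 day 0 replicates 1, 2 and 3, and 73 and 104 without E14 day 15 replicates 1 and 3. It was 87, 84 and 159 without double knockout day 0 replicates 1, 2 and 3, and 182 without its day 15 replicate 1. For the KAT6B knockout 9 of 20635 genes passed (1 higher, 8 lower), among them Sox2 (-2.43 ± 0.33), Lmx1b (-4.03 ± 0.52) and Kank2 (1.42 ± 0.20). That count was 1458 without KAT6B knockout day 15 replicate 1, 3 and 1 without E14 day 15 replicates 2 and 3, and 0 without E14 day 15 replicate 1, KAT6B knockout day 15 replicate 3 or any day 0 library of the pair of lines. For the KAT6A knockout edgeR called 0 of 20604 genes, with 2008 at an unadjusted p under 0.05, DESeq2 called 143, and 1 gene passed without KAT6A knockout day 15 replicate 1.

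**Figure D4:**
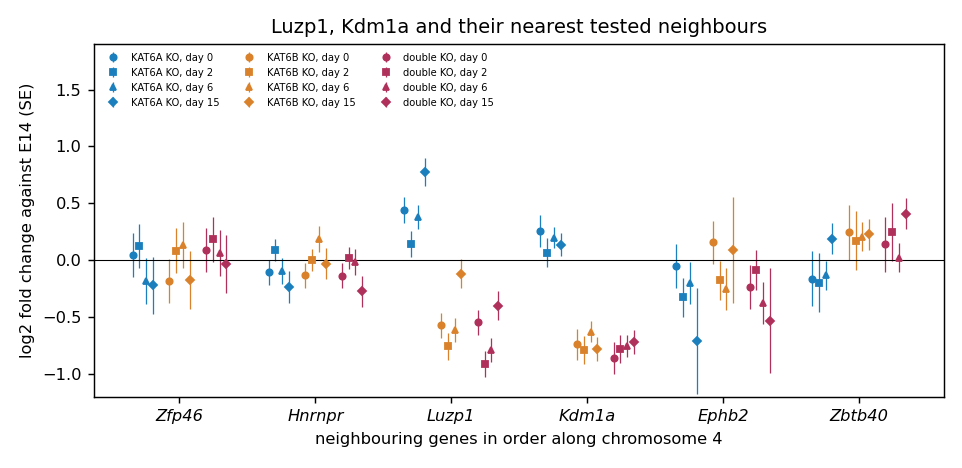
Log2 fold change against E14 (vertical axis, bars are SE) of genes around Luzp1 and Kdm1a in their order along chromosome 4 (horizontal axis), with a point per knockout line and day. In the double knockout at day 6 Luzp1 was at -0.79 and Kdm1a at -0.75.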

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

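Of the tests in this part, the interactions, the search among neighbouring genes, the removal of E14 day 0 replicate 1 and the fit on gene length and expression were planned before their results were seen, and the others were chosen after the result was seen.

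The knockout effect differed between days 15 and 0 by the interaction test for 9 genes in the KAT6B knockout and 518 in the double knockout. The KAT6B knockout genes had log2 differences of 1.42 for Kank2, -4.03 for Lmx1b, -3.68 for Sox2ot, -2.96 for Hopx and -2.43 for Sox2. The double knockout genes had log2 differences of 3.89 for Rspo3, 3.51 for Loxl4, 3.11 for Angptl4, 2.63 for Muc3, -5.48 for Gfap, -4.58 for Mir9-3hg, -4.55 for Rfx4 and -4.50 for Cxcr4. Of 100 splits of the 12 KAT6B knockout and E14 libraries (the real one and a random draw of the others), 3 gave at least 9 genes. The real split is among these 3, and the highest other gave 15. The share is not adjusted over the 3 interactions tested, so chance is not excluded. Of 100 splits for the double knockout, 5 gave at least 518 genes and the highest other gave 1991, so chance is not excluded there. The other splits of an interaction can include one with genotype kept at day 0 and swapped at day 15. Such a split tests a genotype difference shared by both days. The source of the 1991 genes is therefore undecided. For the KAT6A knockout all 100 splits gave at least its 0 genes, the highest 4. With relative log expression size factors the KAT6B knockout count was 0, and Kank2, Lmx1b, Sox2ot, Hopx and Sox2 had log2 differences of 1.55, -3.89, -3.57, -2.83 and -2.30 there.

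The log2 changes of Luzp1 and Kdm1a were negative in the KAT6B knockout and the double knockout, against E14 and against the KAT6A knockout, at the 4 days; the smallest against E14 was -0.12, for Luzp1 in the KAT6B knockout at day 15. Kdm1a lost at least 1.421 CPM for each CPM lost by Luzp1 over 8 comparisons. This cannot exclude reads of Luzp1 counted for the overlapping Kdm1a as the source of its fall. Reads so counted may be missing from the Luzp1 count, and the counting program and its strand setting are not given. The reverse direction was not tested. Chance among neighbours is argued against by 0 other pairs, of 10227 neighbouring pairs, with both members lower by 0.4 or more in the 6 comparisons of these lines with E14 at days 0, 2 and 6; day 15, where Luzp1 itself (-0.12 and -0.40) would not have passed, was not in the search. Loss of 1 copy of the segment in both lines predicts a constant fall of both genes. The mean Kdm1a change of -0.7562 may fit it. Luzp1 went from -0.76 ± 0.12 at day 2 to -0.12 ± 0.12 at day 15 in the KAT6B knockout. In the double knockout it went from -0.91 to -0.40. These Luzp1 values go against a constant fall, so loss of 1 copy is undecided. An event in the lines and an effect of the knockouts cannot be told apart here. The labels name no other line of either genotype, and no DNA was measured.

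Chromosome 8 had the lowest median log2 change of the autosomes in all 9 comparisons of a knockout with E14 at days 0, 2 and 6, between -0.12 and -0.18, and 0.00 to 0.03 at day 15, while chromosome 11 had the highest in the 3 comparisons at day 2 (0.08 to 0.10) and the 3 at day 15 (0.18 to 0.21). All 9 E14 libraries of days 0, 2 and 6 lay above all knockout libraries of their day on the chromosome 8 score, which restates the pattern, and 2 of 3 did at day 15, where the third (0.0228) lay below KAT6B knockout replicate 1 (0.0291). For the double knockout at day 0 the median relative to the other autosomes was -0.1552; low depth of E14 day 0 replicate 1 is argued against by -0.1478 without it, and gene length or expression level by -0.1402 after a fit on both. Extra copies of chromosome 8 in part of the E14 cells and an effect of the knockouts cannot be told apart, since either would give these scores and no DNA was measured. Kat6a itself lies on chromosome 8, so a shift of this size may enter its values.

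Neural progenitor genes were lower as a group in the double knockout at day 15 by the preset correlation, a call lost with an estimated one (adjusted p = 0.247). Whether a lower share of neural cells raised every other type alike was examined with the medians of 4 other lists, which cannot decide it. They were 1.07 for mesenchyme, 0.786 for endoderm, 0.746 for trophoblast and 0.00 for blood, endothelium and heart. The highest and lowest lay 1.063 apart (SE of that difference 0.358, genes taken as independent). That difference rests on the blood list, without which the other 3 lay 0.321 apart. A chi-square test of differences among the medians gave p = 0.0318 over the 4 lists and 0.601 over the other 3. A lower neural share with a rise shared by those 3 types stays open. The 3 E14 scores (4.56 to 4.82) lay above the 9 knockout scores (1.72 to 4.03), with an exact two-sided permutation p of 0.009091, where 0.00455 is the smallest the 220 arrangements allow. This permutation pools the knockout lines and takes libraries as exchangeable, although E14 is 1 line. The list was also chosen after its result in these libraries was seen. The p-value therefore describes the order of these libraries and cannot test an effect of genotype. Lower depth is argued against by a ratio of mean totals of 1.162, double knockout to E14. An effect of the knockouts on neural progenitors and a property of the E14 cultures of day 15 stay open too.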

How the results depend on the processing

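The alternatives were planned, except that the tests leaving out libraries from comparisons that do not hold them were chosen after the results were seen; the cause of a change was not tested unless said. The E14 counts at days 6 and 15 stayed within 1.5 times under every alternative, and that at day 2 under all but leaving out 1 library. Replicates differed by more than counting error, with a chi-square per gene of 6.34 to 435, and edgeR found 8% of simulated 2-fold changes at day 15; what greater depth would add was not tested. In the lists of 4 values below, the order is days 0, 2, 6 and 15, and counts within 1.5 times are left out.

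With relative log expression size factors 28 of 30 counts stayed within 1.5 times, and the KAT6B knockout at day 6 gave 2 (1 higher, 1 lower, where the main scaling gave 2 and 4) and its interaction 0, while the higher share of the double knockout genes at day 15 went from 58.5% to 50.4%. The median change of all genes moved by more than 0.1 only for that interaction, from -0.07 to 0.06. At least 1 CPM in at least 3 libraries left 29 of 30, and the single knockouts at day 2 differed in 2. Without a filter 16 of 30 stayed. More genes then passed: 2 for the KAT6A knockout at day 0; 48, 4 and 59 for the KAT6B knockout at days 0, 2 and 6; 33 for the double knockout at day 6. The double knockout gave 36 and 11 against the KAT6A knockout at days 0 and 2, and 23, 29 and 96 against the KAT6B knockout at days 0, 2 and 6. The single knockouts gave 8, 15 and 5 at days 0, 2 and 6, and the KAT6B knockout interaction 23.

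DESeq2 called more genes in all 30 comparisons, over 1.5 times as many in all but the 3 of the E14 time course, and on simulated data it also made more false calls. It gave 5, 28, 2 and 280 for the KAT6A knockout, 194, 23, 534 and 1720 for the KAT6B knockout and 1087, 644, 243 and 2593 for the double knockout. The double knockout gave 127, 110, 11 and 61 against the KAT6A knockout and 140, 219, 641 and 72 against the KAT6B knockout, and the single knockouts 32, 134, 460 and 31. Interactions gave 143, 712 and 1656 in the KAT6A, KAT6B and double knockout. Called in the same direction in both single knockouts were 2, 4, 2 and 227.

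With all 48 libraries in 1 fit, 16 counts were over 1.5 times higher and 7 lower. The KAT6A knockout gave 1, 1 and 730 at days 0, 6 and 15, the KAT6B knockout 1, 2, 22 and 3186, and the double knockout 58, 35 and 4397 at days 0, 2 and 15. The double knockout gave 2 and 91 against the KAT6A knockout at days 0 and 15, and 1, 0, 42 and 89 against the KAT6B knockout. The single knockouts gave 3, 8, 4 and 56, and the interactions 2, 971 and 1174. This fit estimates 1 spread per gene over all days, although the spread differed between days.

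With only the 2 groups compared in the fit, with fewer libraries to estimate the spread, 4 counts were higher and 12 lower. The KAT6B knockout gave 0, 1 and 0 at days 0, 6 and 15, and the double knockout 40, 419, 1 and 2397. The double knockout gave 78, 0, 0 and 0 against the KAT6A knockout and 0, 0 and 19 against the KAT6B knockout at days 0, 2 and 6. The single knockouts gave 0 and 1 at days 2 and 6.

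With a replicate block, a term for the replicate number, the KAT6B knockout gave 26, 371 and 0 at days 0, 6 and 15, the double knockout 606, 39 and 0, and the KAT6A knockout 1 at day 2. The double knockout gave 25, 5 and 0 against the KAT6A knockout at days 0, 2 and 15, and 27, 4 and 194 against the KAT6B knockout at days 0, 2 and 6, and the single knockouts 6 at day 6. In the 4 comparisons whose libraries the numbers pair, the block changed no call of a named gene or list other than those of Grb10, Kat6a and Col1a2. In the other 23 of 27, at least 1 same-number correlation was 0.1 or less, so whether the numbers pair those libraries is undecided. Over all, 33 of 72 same-number pairs correlated above 0.1 (from -0.51 to 0.56), and 29 of 48 libraries matched their own number best, where chance gives 16. At days 0, 2 and 6 it was 8, 8 and 9 of 12 libraries, and at day 15 it was 4, where chance gives 4 at each day.

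Leaving out 1 library left 102 counts within 1.5 times, raised 23 and lowered 97. Most of these fits had fewer libraries in a group compared. The others left out a library of neither group, and gave the upper ends 440, 31 and 2579 of the double knockout below. The ranges were 1985 to 5483 for E14 at day 2; 0 to 1 and 0 to 2 for the KAT6A knockout at days 0 and 2; 0 to 1164, 0 to 3, 0 to 3 and 0 to 1949 for the KAT6B knockout; and 80 to 1942, 7 to 440, 0 to 31 and 0 to 2579 for the double knockout. The double knockout ranged over 0 to 24, 0 to 35 and 0 to 1 against the KAT6A knockout at days 0, 2 and 15, and 0 to 15, 0 to 7 and 0 to 1 against the KAT6B knockout at days 0, 2 and 6. The single knockouts ranged over 0 to 8, 0 to 2 and 0 to 4 at days 0, 2 and 6. Interactions ranged over 0 to 1, 0 to 1458 and 73 to 1130. The correlation of the single knockouts ranged over 0.473 to 0.757, 0.244 to 0.686, 0.0920 to 0.657 and 0.621 to 0.790, with 0 to 1 genes called in both at days 0 and 2.

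No result reversed. Of the named gene values, DESeq2 left 1000 on their side of the threshold and moved 33 past it. Leaving out 1 library left 5171, ended 915 calls and brought 25 past the threshold. It moved 207 values not called in the main fit by more than the SE of their main log2 change. An estimated correlation ended 150 list calls and left 210 list tests on their side of the threshold. The self-contained test fry ended 96 list calls, brought 7 past the threshold and left 257. By fry 0 lists passed in the KAT6A knockout at any day, 0, 1, 1 and 2 in the KAT6B knockout and 6, 3, 2 and 1 in the double knockout.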

Other observations

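The list tests in this part were planned, and the tests on other splits of the libraries were chosen after the result was seen.

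Gene lists outside the pluripotent and neural programs also moved. In the E14 time course imprinted genes rose as a group: at day 6, 12 of 24 rose and 3 fell (median 0.47, camera adjusted p = 0.0103), and at day 15, 15 rose and 3 fell (median 1.17, adjusted p = 0.00538), with the same counts when adjusted over the list alone. Germline genes were lower at day 15 (1 of 16 rose and 13 fell, also over the list alone, median -2.82, adjusted p = 0.00486), among them Sycp3, of the meiotic chromosome axis, which went from 11 ± 3.57 to 0.59 ± 0.36 CPM. These 3 calls were lost with an estimated correlation, at adjusted p = 0.314, 0.282 and 0.527. Hox genes, lower at day 2 (0 of 33 rose, 10 fell, 14 over the list alone, median -1.75, adjusted p = 5.06e-07), had 25 rising and 1 falling at day 15, also over the list alone (median 6.07, adjusted p = 1.18e-10). The Hox calls were lost with an estimated correlation, at adjusted p = 0.188 and 0.122. Neural crest and peripheral neuron genes did not pass as a group at day 15 (10 of 13 rose and 3 fell, also over the list alone, median 2.44, adjusted p = 0.06), nor did primitive streak genes (3 rose and 6 fell, also over the list alone, median -1.92, adjusted p = 0.628). For primitive streak genes at day 2 the median (0.10) and the test (down, adjusted p = 0.792) differed in sign.

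Against E14, the knockouts differed in some of these lists. Hox genes were lower at day 15 in the KAT6A knockout (0 of 33 over all genes or the list alone, median -0.78, adjusted p = 0.0106) and in the KAT6B knockout (0 of 33, 2 fell over the list alone, median -1.03, adjusted p = 1.97e-05), and both calls held in all 6 fits that left out 1 library. In the double knockout the Hox call (1 of 33 rose, with 3 rising and 10 falling over the list alone, median -1.40, adjusted p = 0.0166) was lost without double knockout replicate 3 (adjusted p = 0.335). With an estimated correlation the 3 calls were lost, at adjusted p = 0.615, 0.427 and 0.635. Neural crest genes were lower in the double knockout at day 15 (2 of 13 fell, with 1 rising and 5 falling over the list alone, median -1.16, adjusted p = 0.00949), a call lost without its replicate 3 (adjusted p = 0.0921) and with an estimated correlation (adjusted p = 0.57). In double knockout stem cells imprinted genes were higher as a group (2 of 23 rose and 1 fell, with 6 and 2 over the list alone, median 0.24, adjusted p = 0.0134), which was lost without E14 replicate 1 (adjusted p = 0.0774) and with an estimated correlation (adjusted p = 0.247). There primitive streak genes were lower (1 of 14 rose and 1 fell, with 1 and 3 over the list alone, median -0.77, adjusted p = 0.0128), a call lost without E14 replicate 3 or double knockout replicate 2 (adjusted p up to 0.189) and with an estimated correlation (adjusted p = 0.556). Germline genes were higher in the KAT6A knockout at day 6 (0 of 16 over all genes or the list alone, median 0.47, adjusted p = 0.000999), lost without E14 replicate 1 or 3 (adjusted p up to 0.0563) and with an estimated correlation (adjusted p = 0.615). In the KAT6B knockout they were lower at that day (0 of 16 over all genes or the list alone, median -0.48, adjusted p = 0.00503), lost without E14 replicate 2 or KAT6B knockout replicate 1 (adjusted p up to 0.615) and with an estimated correlation (adjusted p = 0.707). Those of the double knockout were higher (0 of 16 over all genes or the list alone, median 0.36, adjusted p = 0.0377), lost without E14 replicate 1 or 3 or double knockout replicate 1 or 2 (adjusted p up to 0.515) and with an estimated correlation (adjusted p = 0.781).

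The 6 libraries of each comparison make 10 splits into groups of 3, too few for a share under 0.05. In the E14 time course 1 of the 10 splits, the real one, gave as many genes at each day: 4426, 10257 and 14289 at days 2, 6 and 15, with a highest other of 0 each. For the double knockout against E14 it was 1 of 10 at each day, with 396, 220, 14 and 643 genes and a highest other of 0. For the KAT6B knockout 1, 10, 1 and 1 of 10 splits gave at least the 2, 0, 6 and 15 genes at days 0, 2, 6 and 15, and the highest others were 0, 2, 0 and 0. For the KAT6A knockout 10, 2, 10 and 10 splits gave at least the 0, 2, 0 and 0 genes, and the highest others were 0, 2, 675 and 0. A split calling 675 genes where the real one called 0 points to a structure of the day 6 libraries other than genotype.

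Between knockout lines, with 10 splits again too few for a share under 0.05, the double knockout against the KAT6A knockout gave at least its 10, 3, 2 and 1 genes in 1, 3, 1 and 1 splits at the 4 days, with highest others of 0, 132, 0 and 0. Against the KAT6B knockout it gave at least its 12, 2, 0 and 0 genes in 1, 1, 10 and 10 splits, with highest others of 0, 1, 0 and 0. The single knockouts gave at least their 5, 1, 2 and 0 genes in 1, 1, 1 and 10 splits, with highest others of 0, 0, 0 and 14. The 132 genes at day 2 and the 14 at day 15 came from splits that cut across genotype, which points to a structure of those libraries too. In the 4 comparisons whose libraries the numbers pair, the 3 other splits that part all 3 pairs gave 0 genes each. The 6 that part 1 pair gave up to 132 in the double knockout against the KAT6A knockout at day 2, where the replicate block gave 5 for the real split, and 0 in the other 3 comparisons.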
